A study of Homo sapiens with 27 samples.

How the data were processed

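Polyadenylated RNA of 27 cultures of the breast cancer lines T47D, TYS and TDG had been sequenced as stranded libraries on an Illumina instrument. Per the labels, cells were depleted of hormone for 48 hours in medium with charcoal-dextran treated fetal bovine serum and 96 hours in medium with treated calf serum, and then received vehicle or 10 nM estradiol. T47D was otherwise kept in 10% fetal bovine serum and the mutant lines in 10% charcoal-dextran treated serum. According to the submitters' notes, the authors made reads with bcl2fastq 2.17.1.14, checked them with FastQC 0.11.5, aligned them with STAR 2.5.1b to GRCh38.p10 and counted them with Subread 1.5.0. They also named edgeR, without giving its role. The deposited values are raw read counts per gene, and per the file headers they were made by featureCounts 1.5.0 with the strand option 2 over the exons of Ensembl release 88, without an option for reads with several positions.

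Gene symbols were taken from GENCODE 29 for 57895 of the 58233 genes, while 338 had none, and coordinates came from the deposited counts. Each library was grouped by line and treatment as its label states, in 9 groups of 3. Total counts were 25456771 to 36959220, which puts the level of 3 counts at 0.0812 to 0.118 CPM, the count scaled to a common library total. Genes were kept with the filterByExpr function of edgeR 4.0.16 (smallest count 10, smallest total 15), which left 16512. Counts were scaled by TMM, and 1 quasi-likelihood model with a term per group and robust dispersions was fitted to the 27 libraries, with 18 residual degrees of freedom and a common biological coefficient of variation of 6.4%. From this fit came 13 two-sided contrasts, 9 of them between groups and 4 interactions of line and estradiol. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Standard errors of log2 changes came from a voom fit of the same design in limma 3.58.1. Principal components used log2 CPM with a prior count of 2 and the 1000 most variable genes.

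The genes named in the text followed a rule. A panel of 9 genes was given for each comparison between groups. To it were added up to 5 genes per direction with the largest log2 change (4 for interactions) among called genes with a mean of at least 5 CPM, a name other than a clone or LINC name and, outside interactions, groups that did not overlap. Up to 3 called members of each described list completed the set, and the text gives a part of these genes. Of 22 gene lists, 19 with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, with p-values adjusted over the 19 lists, and again with an estimated correlation. The lists were estrogen-induced genes, estrogen-repressed genes, nucleolar and growth MYC targets, G1/S and DNA replication genes, G2/M and mitosis genes, G1 regulators, unfolded protein response genes, ATF4 and amino acid response genes, aminoacyl-tRNA synthetases, ribosomal proteins, cholesterol synthesis genes, interferon-stimulated genes, hypoxia and glycolysis genes, luminal epithelial markers, basal and mesenchymal markers, BCL2 family genes, immediate early genes, heat shock genes and mitochondrially encoded genes. The text describes a part of these lists in each comparison, and some of the others also passed the test with the preset correlation. Adjusted p-values with an estimated correlation accompany the described lists that lost their call with it. Described lists given without one also passed with it, or did not pass at the preset correlation. Markers of fibroblasts, immune cells and endothelium had too few tested members for camera. The groups, contrasts, gene rule, lists and all alternatives but 2 were chosen before the data were examined.

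The alternatives were DESeq2 size factors in edgeR, no scaling beyond the library total, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a fit of only the libraries compared, the replicate number as a block, an estimated correlation for the lists, and leaving out each library in turn. Added after the data were seen were the fits without both T47D libraries with a length trend and with trends of transcript length and GC content removed. Shared calls between comparisons were set against 20 simulations of unchanged genes with the same shared libraries. The test was tested on simulated data with 50 genes changed per size, made for 4 hours of E2 against vehicle in T47D. It recovered 22%, 88%, 88% and 100% of the genes at 1.2, 1.5, 2 and 4-fold, with 2.6% of its calls false. For the TYS interaction at 4 hours it recovered 4%, 64%, 84% and 98%, and 8.1% of the calls were false, above the 5% aimed at. Simulated counts were drawn independently, with no length trend in any library and few genes changed. The shares therefore need not hold for the real libraries. The work ran in R 4.3.3 with the data.table package (1.17.8) and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Reads were not used here, and XIST and genes of the Y chromosome were left out of the named genes.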

Results

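Polyadenylated RNA was sequenced from 3 human breast cancer lines grown without hormone and then given vehicle or estrogen. T47D carries wild-type ESR1, the gene of estrogen receptor alpha, while TYS and TDG carry the ESR1 changes Y537S and D538G in its ligand-binding domain. Cells of each line received ethanol as vehicle, sampled at 4 hours, or 10 nM estradiol (E2) for 4 or 24 hours. The 9 groups held 3 biological replicates each, 27 libraries in all. Total counts per library ran from 25456771 to 36959220. In these libraries, a gene without any count lay below 0.0812 to 0.118 CPM, the count scaled to a common library total, the level of 3 counts. These floors cover counting error only.

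The libraries grouped by line first and, within T47D and TDG, by treatment. Of the 27 libraries, 25 correlated best with a library of their own group, while TYS vehicle replicate 3 was closest to a TYS library after 4 hours of E2 and TYS E2 4 h replicate 1 to a TYS vehicle library. The first principal component held 66.4% of the variance of the 1000 most variable genes and set TYS apart from T47D. The second, with 20.9%, set TDG apart. T47D libraries given E2 lay apart from vehicle on both components, those of 24 hours further than those of 4 hours, with no 24 hour vehicle to set them against, while the TYS libraries of all treatments lay close together. Within groups, log2 CPM correlated across genes at r = 0.9907 to 0.9955, where genes are not independent replicates. T47D vehicle replicate 1 and T47D E2 24 h replicate 2 stood apart from their replicates, with relatively more counts in short transcripts (Spearman correlation of the deviation with transcript length across genes -0.709 and -0.702).

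**Figure D1:**
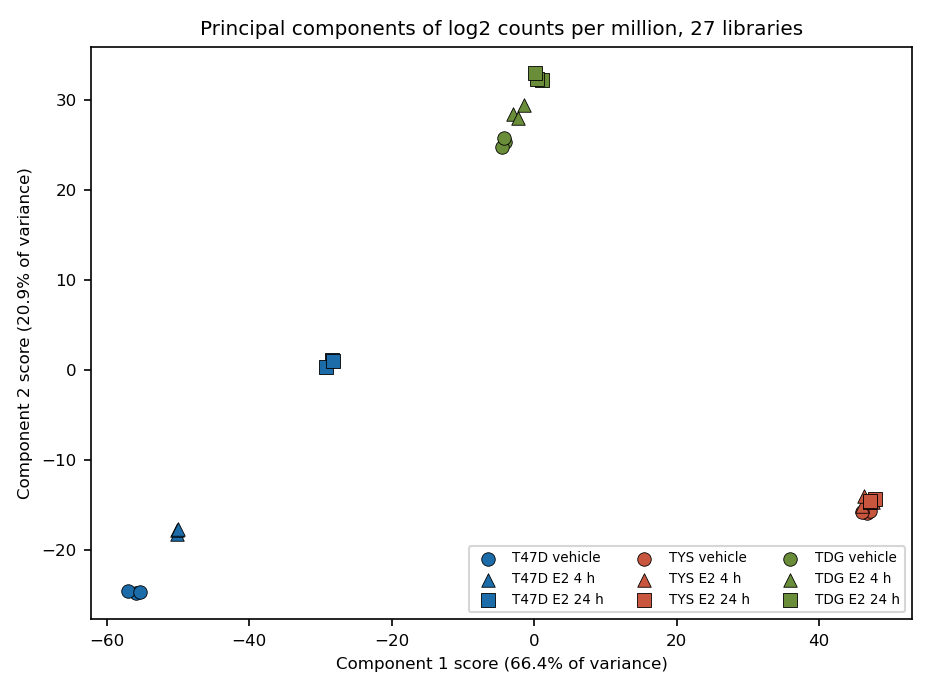
Scores of the 27 libraries on the first and second principal components of log2 CPM, with colour for the line and marker shape for the treatment. On component 1, T47D vehicle libraries lie at -56.98 to -55.37, T47D libraries after 24 hours of E2 at -29.18 to -28.2 and TYS libraries at 45.98 to 47.83.

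A panel of 9 genes was followed in every comparison of vehicle and E2 libraries (coordinates on GRCh38). ESR1 (ENSG00000091831) lies on chromosome 6 from 151656691 to 152129619. The transcription factor gene MYC (ENSG00000136997) lies on chromosome 8 from 127735434 to 127741434, and CCND1 (ENSG00000110092), the gene of cyclin D1, on chromosome 11 from 69641087 to 69654474. Known estrogen-responsive genes were PGR, the progesterone receptor gene (ENSG00000082175, chromosome 11, 101029624 to 101130524), GREB1 (ENSG00000196208, chromosome 2, 11482341 to 11642788) and TFF1, a trefoil peptide gene (ENSG00000160182, chromosome 21, 42362282 to 42366594). The others were PDZK1 (ENSG00000174827, chromosome 1, 145670852 to 145708148) and the chemokine gene CXCL12 (ENSG00000107562, chromosome 10, 44370165 to 44386493). The proliferation marker gene MKI67 (ENSG00000148773) lies on chromosome 10 from 128096659 to 128126385. Below, CPM values are group means ± SD (n = 3 per group), log2 changes are given ± SE, and adjusted p-values come from edgeR over the 16512 genes tested. Largest changes of single genes are ranked among called genes with a mean of at least 5 CPM, and genes of lower level can change more.

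**Figure D2:**
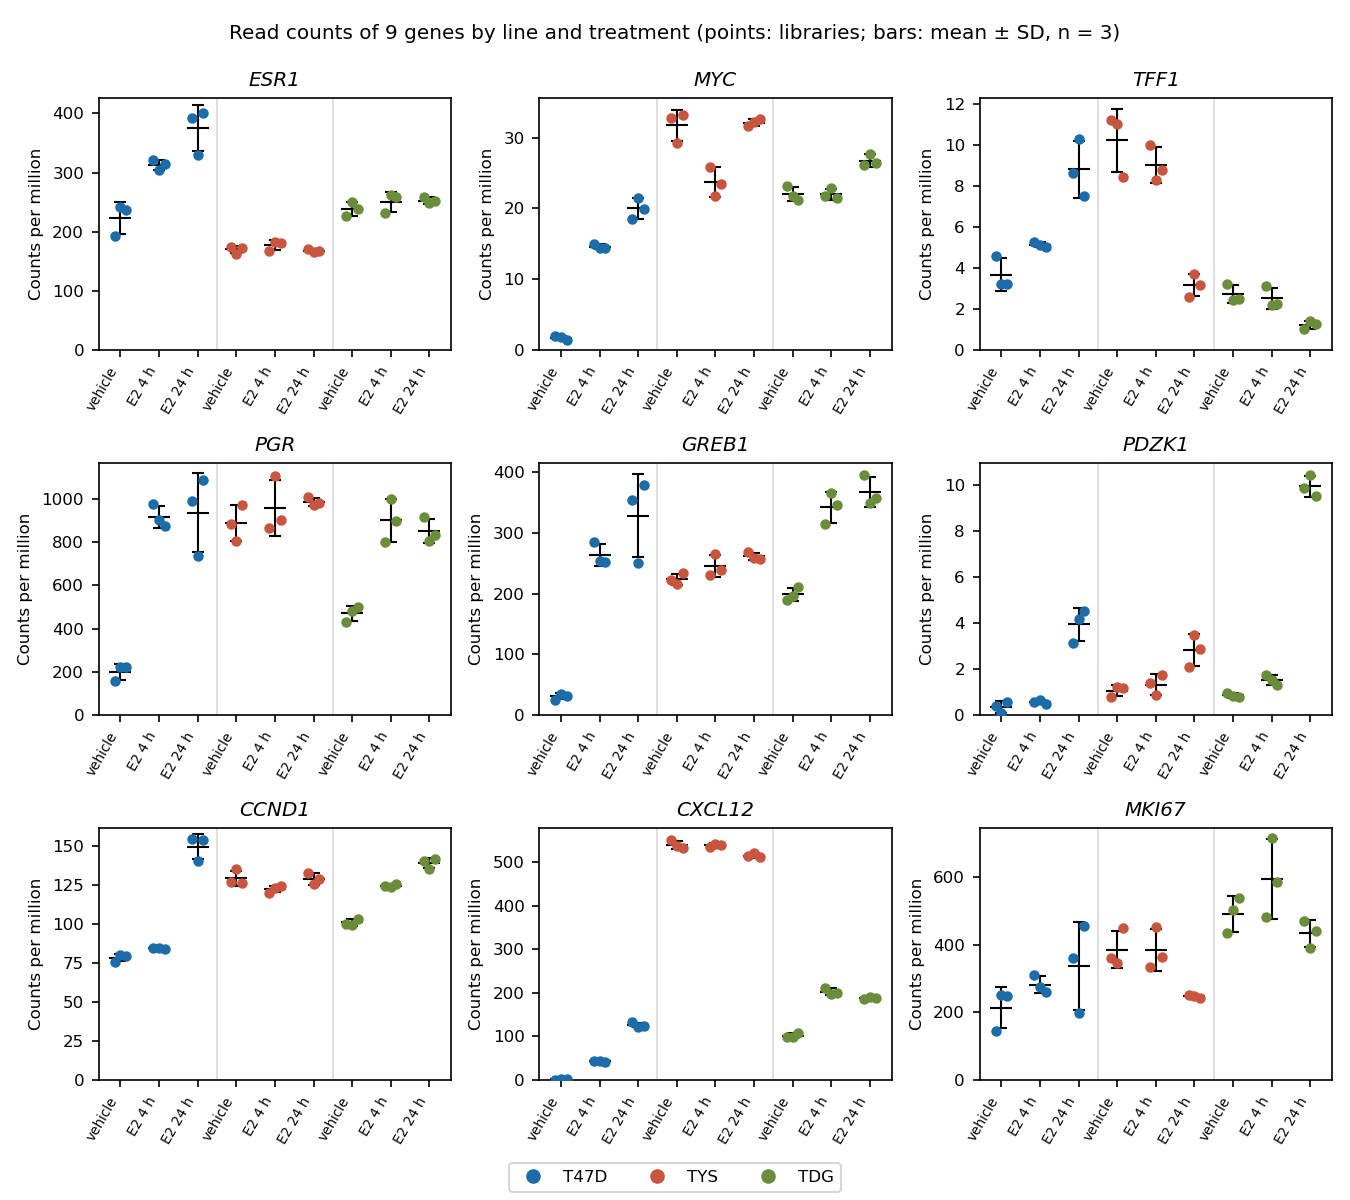
CPM of the 9 panel genes in each line and treatment, with points for libraries and bars for the mean ± SD (n = 3). MYC lies at 1.74 CPM in T47D vehicle and at 22.1 and 31.8 CPM in TDG and TYS vehicle.

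The vehicle libraries addressed how cells with a mutant receptor differ from wild-type cells when no hormone is given. In TYS, MYC stood at 31.8 ± 2.22 CPM against 1.74 ± 0.29 CPM in T47D, a log2 change of 4.19 ± 0.14 (adjusted p = 3.35e-24). CXCL12 showed the largest rise at that level, from 1.38 ± 0.207 to 540.5 ± 9.48 CPM (log2 change 8.61 ± 0.13, adjusted p = 1.95e-34). GREB1 rose by 2.87 ± 0.13 (adjusted p = 4.66e-16), PGR by 2.14 ± 0.14 (adjusted p = 1.92e-12) and TFF1 by 1.48 ± 0.16 on the log2 scale (adjusted p = 7.02e-10). CCND1 rose by 0.72 ± 0.04 (adjusted p = 1.07e-14) and PDZK1, at 1.07 CPM in TYS, by 1.62 ± 0.48 (adjusted p = 0.000376). ESR1 itself was lower, with a log2 change of -0.40 ± 0.07 (adjusted p = 1.32e-05). Other large rises were those of BCHE, which encodes butyrylcholinesterase, from 0.45 to 94.6 CPM, of ADRA2A, an adrenergic receptor gene, from 0.247 to 30.4 CPM, and of CYP4F22 from 0.153 to 18.1 CPM. The largest falls among genes with a mean of at least 5 CPM were those of CHST1, from 33.5 to 0.27 CPM, of ATP13A4, from 19.8 to 0.147 CPM, and of LRRC15, from 16.5 to 0.105 CPM, which rested on 25, 14 and 10 counts in the 3 TYS libraries. In all, 5979 genes were higher and 6466 lower in TYS, of which 1865 and 2998 changed at least 2-fold, while the 1 CPM filter gave 5719 higher and 5515 lower. Without T47D vehicle replicate 3 the log2 changes were 2.207 for PDZK1, 7.561 for ADRA2A and 7.63 for CYP4F22, against 1.618, 6.911 and 6.839 with it.

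Genes that estrogen is known to induce were mostly raised in TYS without hormone. Of 37 tested, 34 were higher and 2 lower (median log2 change 1.58, camera adjusted p = 4.19e-12). Among them were the potassium channel gene KCNK5 (5.46 ± 0.17) and OLFM1 (4.78 ± 0.07). Of 14 genes that estrogen is known to repress, 13 were lower and 0 higher (median -2.07, camera adjusted p = 1.58e-08). The largest of these falls were those of BCAS1 (-4.87 ± 0.06) and the interleukin-1 receptor gene IL1R1 (-4.05 ± 0.11). Nucleolar and growth genes known as MYC targets rose as a group, 51 of 53 higher and 0 lower (median 1.15, camera adjusted p = 1.86e-18). Examples were PRMT3 (2.51 ± 0.06), the folate carrier gene SLC19A1 (2.14 ± 0.08) and TCOF1, which encodes a nucleolar protein (2.13 ± 0.05). Of 40 genes of the G1/S transition and DNA replication, 39 were higher and 0 lower (median 1.21, camera adjusted p = 1.86e-18). They included UHRF1 (2.11 ± 0.05) and the replicative helicase genes CDC45 (2.04 ± 0.06) and MCM2 (1.93 ± 0.04). Of 53 genes of G2/M and mitosis, 49 were higher and 0 lower (median 0.59, camera adjusted p = 4.19e-12). They included CDC20 (1.65 ± 0.05) and AURKB (1.61 ± 0.07). The proliferation marker MKI67 rose by 0.85 ± 0.24 on the log2 scale (adjusted p = 0.00337).

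Several other gene groups differed between TYS and T47D without hormone, with set tests that depended on the correlation assumed between genes. Of 81 cytosolic ribosomal protein genes, 79 were higher in TYS and 1 lower (median 0.69, camera adjusted p = 1.49e-11, against an adjusted p = 0.402 with an estimated correlation). The mean of this list was 8.70 log2 CPM in T47D vehicle replicate 1, the library with more counts in short transcripts, against 8.25 and 8.24 in the other T47D vehicle libraries and 8.99 to 9.20 in TYS. Of 18 cytosolic aminoacyl-tRNA synthetase genes, 15 were higher and 2 lower (median 0.39, camera adjusted p = 0.000261, and adjusted p = 0.195 with an estimated correlation), for example KARS (1.28 ± 0.05) and VARS (1.27 ± 0.04). Interferon-stimulated genes were lower in TYS, 25 of 29 with 2 higher (median -2.45, camera adjusted p = 2.58e-05, and adjusted p = 0.29 with an estimated correlation). OAS2 stood at 1.63 ± 0.106 against 82.95 ± 39.4 CPM and IFI27 stood at 0.401 ± 0.0779 against 19.4 ± 4.37 CPM. Their mean was 4.17 log2 CPM in T47D vehicle replicate 2 against 3.57 and 3.51 in the other T47D vehicle libraries. Of 21 luminal epithelial markers, 15 were lower and 1 higher (median -0.40, camera adjusted p = 0.000239, and adjusted p = 0.0518 with an estimated correlation). They included the mucin gene MUC1 (-1.80 ± 0.07) and the epithelial transcription factor gene ELF3 (-2.18 ± 0.05). Adjusted over the list alone, each list named for this comparison gave the same counts. TYS and T47D differed in routine culture serum as well as in ESR1, and with 1 line per genotype these cannot be separated.

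TDG showed a similar set of changes without hormone. It too differed from T47D in routine culture serum as well as in ESR1, and these cannot be separated. MYC stood at 22.1 ± 1.02 CPM against 1.74 ± 0.29 CPM in T47D (log2 change 3.66 ± 0.15, adjusted p = 4.36e-22). CXCL12 reached 101.9 ± 5.08 CPM (6.2 ± 0.13, adjusted p = 1.39e-30), GREB1 rose by 2.70 ± 0.13 (adjusted p = 2.68e-15) and PGR by 1.23 ± 0.14 on the log2 scale (adjusted p = 2.93e-08). CCND1 rose by 0.36 ± 0.04 (adjusted p = 2.96e-08), PDZK1 by 1.31 ± 0.49 (adjusted p = 0.00506) and MKI67 by 1.2 ± 0.24 (adjusted p = 0.000182). TFF1, at 2.72 against 3.67 CPM, had a log2 change of -0.44 ± 0.20 (adjusted p = 0.0347), a call that was lost in 6 of the alternative settings, among them the fit without T47D vehicle replicate 1 (-0.25) and those without TDG vehicle replicate 2 or 3 (-0.34 and -0.37). ESR1 was not called (0.09 ± 0.07, adjusted p = 0.258), and its change was 0.18 and passed the test without T47D vehicle replicate 2, 0.109 and passed with length and GC trends removed, and -0.008 without replicate 1. Large rises were also seen for NXPH3 (4.99 ± 0.24), the peroxisomal oxidase gene ACOX2 (4.87 ± 0.27) and CYP2S1 (3.75 ± 0.16). IQCN, at 0.274 CPM and 24 counts in TDG (-5.86 ± 0.41), and the water channel gene AQP3 (-5.19 ± 0.24) were among the largest falls at that level. In all, 5552 genes were higher and 5799 lower in TDG than in T47D, of which 1382 and 2149 changed at least 2-fold, and the 1 CPM filter gave 5358 and 5062.

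By gene group, 31 of the 37 estrogen-induced genes were higher in TDG and 4 lower (median 1.23, camera adjusted p = 5.05e-11), and 12 of 14 estrogen-repressed genes were lower and 0 higher (median -1.19, camera adjusted p = 1.69e-07). The receptor gene ERBB2 (-1.86 ± 0.05) and the cyclin gene CCNG2 (-1.93 ± 0.06) were among these. Of the 53 MYC targets, 51 were higher and 0 lower (median 0.91, camera adjusted p = 2.3e-19), as were 39 of 40 G1/S genes with 1 lower (median 0.98, camera adjusted p = 1.96e-18) and 52 of 53 G2/M genes with 1 lower (median 0.73, camera adjusted p = 3.71e-19). Among these, the primase gene PRIM1 rose by 1.79 ± 0.06, MCM5 by 1.64 ± 0.05 and CDC20 by 1.32 ± 0.05 on the log2 scale. Hypoxia and glycolysis genes were mostly lower, 15 of 24 with 3 higher (median -0.36, camera adjusted p = 0.0197, and adjusted p = 0.242 with an estimated correlation). The stress gene NDRG1 fell from 137.8 ± 6.25 to 4.88 ± 0.599 CPM and EGLN3, which encodes a HIF prolyl hydroxylase, from 31.9 ± 2.46 to 1.01 ± 0.20 CPM, while PFKFB3, a regulator of glycolysis, rose by 1.76 ± 0.05. Aminoacyl-tRNA synthetase genes were higher, 14 of 18 with 1 lower (median 0.48, camera adjusted p = 7.51e-06, and adjusted p = 0.0986 with an estimated correlation). Interferon-stimulated genes were lower, 23 of 29 with 1 higher (median -1.30, camera adjusted p = 0.000197, and adjusted p = 0.316 with an estimated correlation), beside the T47D vehicle library with the high mean named above and list means of 2.46, 2.56 and 3.06 log2 CPM in TDG vehicle replicates 1, 2 and 3. Luminal markers were lower in 12 of 21 cases and higher in 4 (median -0.28, camera adjusted p = 0.0207, and adjusted p = 0.211 with an estimated correlation). AZGP1 of this list was 4.01-fold higher in TDG and 9.05-fold lower in TYS than in T47D. The 81 ribosomal protein genes gave 27 higher and 7 lower (median 0.11, camera adjusted p = 0.0609), with an adjusted p = 1.38e-05 without T47D vehicle replicate 1 and 0.0192 without TDG vehicle replicate 2. The ribosomal counts adjusted over the list alone were 27 and 6, and the other lists named for this comparison gave the same counts.

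Compared directly without hormone, TYS was further from T47D than TDG for the estrogen-regulated groups. With 1 line per genotype, the replicates are cultures of that line. Differences between TYS and TDG therefore cannot be credited to their ESR1 changes rather than to other differences between the lines. MYC was higher in TYS than in TDG by 0.53 ± 0.07 (adjusted p = 2.74e-07), CXCL12 by 2.41 ± 0.04 (adjusted p = 1.02e-24), PGR by 0.91 ± 0.13 (adjusted p = 3.65e-06), TFF1 by 1.91 ± 0.17 (adjusted p = 3.02e-11) and CCND1 by 0.36 ± 0.04 on the log2 scale (adjusted p = 6.68e-08). ESR1 was lower in TYS (-0.49 ± 0.07, adjusted p = 1.2e-06), while GREB1 (0.17 ± 0.11, adjusted p = 0.202), PDZK1 (0.31 ± 0.35, adjusted p = 0.413) and MKI67 (-0.35 ± 0.24, adjusted p = 0.214) were not called. GREB1 passed without a filter (0.19) and in a fit of the 6 libraries alone (0.163), as MKI67 did (-0.333 and -0.36) and again with length and GC trends removed (-0.439). Of the estrogen-induced genes, 22 were higher in TYS and 7 lower (median 0.57, camera adjusted p = 2.76e-05). The growth factor gene AREG was 7.66-fold higher and the protease gene PRSS23 7.58-fold lower. Of the estrogen-repressed genes, 11 were lower in TYS and 1 higher (median -0.75, camera adjusted p = 1.72e-06). Of 27 genes of the unfolded protein response, 20 were lower in TYS and 2 higher (median -0.38, camera adjusted p = 6.76e-06). Among them were the chaperone genes CALR (-1.29 ± 0.07) and HSP90B1 (-0.98 ± 0.06) and the stress gene DDIT3 (-1.85 ± 0.12). Among genes with a mean of at least 5 CPM, large single differences were BCHE (6.28 ± 0.17), TMTC1 (6.13 ± 0.26) and the collagen gene COL4A6 (5.76 ± 0.22) on the higher side and PRKAA2, a kinase subunit gene with 22 counts in TYS, on the lower side (-5.82 ± 0.52). In all, 4643 genes were higher and 4746 lower in TYS than in TDG, a balance that turned in 3 settings (4818 and 4615 without a filter). It was less even without scaling (3905 and 5483) and with length and GC trends removed (4619 and 5517).

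Other groups differed between the mutant lines with the preset correlation but not with an estimated one. MYC targets were higher in TYS in 33 of 53 cases and lower in 2 (median 0.24, camera adjusted p = 1.58e-05, and adjusted p = 0.339 with an estimated correlation). G1/S genes were higher in 27 of 40 and lower in 3 (median 0.29, camera adjusted p = 6.19e-07, and adjusted p = 0.113 with an estimated correlation), for example NASP (0.88 ± 0.06) and the polymerase gene POLA1 (0.79 ± 0.05). G2/M genes went the other way, lower in 25 of 53 and higher in 10 (median -0.13, camera adjusted p = 0.0416, and adjusted p = 0.362 with an estimated correlation), for example NEK2 (-0.68 ± 0.05). The adjusted p was 0.0744 and 0.094 without TDG vehicle replicate 1 or 3 and 0.0503 without TYS vehicle replicate 1. Luminal markers were lower in 15 of 21 and higher in 5 (median -0.27, camera adjusted p = 0.00475, and adjusted p = 0.171 with an estimated correlation), with the keratin gene KRT18 lower (-1.22 ± 0.07) and TFF3 higher (1.32 ± 0.15). Ribosomal protein genes were higher in 68 of 81 and lower in 1 (median 0.57, camera adjusted p = 1.18e-13, and adjusted p = 0.426 with an estimated correlation). Hypoxia and glycolysis genes were higher in 14 of 24 and lower in 2 (median 0.31, camera adjusted p = 0.000198, and adjusted p = 0.113 with an estimated correlation). Interferon-stimulated genes were lower in 21 of 29 and higher in 4 (median -1.23, camera adjusted p = 0.00206, and adjusted p = 0.516 with an estimated correlation), beside the TDG vehicle means given above. Mitochondrially encoded genes were lower in 12 of 13 and higher in 0 (median -0.48, camera adjusted p = 0.00188, and adjusted p = 0.484 with an estimated correlation). The mean of the last list was 10.74 log2 CPM in TDG vehicle replicate 3 against 11.15 and 11.13 in the other TDG vehicle libraries. Counts adjusted over the list alone, higher and lower, were 28 and 3 for the G1/S genes, 11 and 25 for the G2/M genes, 70 and 1 for the ribosomal genes, 15 and 2 for the hypoxia genes, 2 and 21 for the unfolded protein response and 0 and 13 for the mitochondrial genes, and those of the other lists named for this comparison did not differ.

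**Figure D3:**
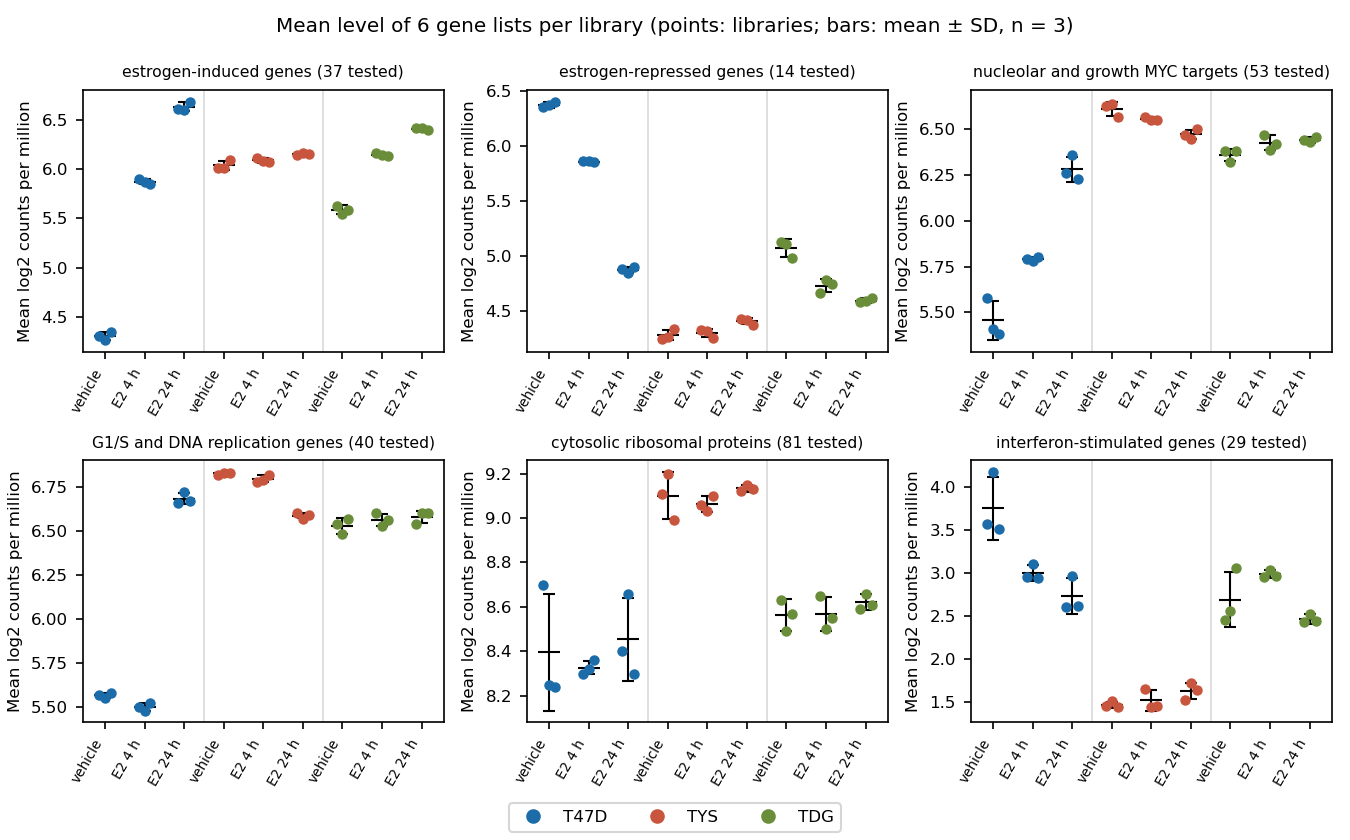
Mean log2 CPM of 6 gene lists in each library, with points for libraries and bars for the mean ± SD (n = 3), by line and treatment. The interferon-stimulated genes reach 4.17 in T47D vehicle replicate 2 and the ribosomal protein genes 8.70 in T47D vehicle replicate 1, above the other libraries of that group.

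A treatment of 4 hours with E2 in T47D addressed the early response of the wild-type receptor. MYC rose from 1.74 ± 0.29 to 14.6 ± 0.349 CPM (log2 change 3.07 ± 0.15, adjusted p = 2.24e-19). CXCL12 rose by 4.97 ± 0.13 (adjusted p = 1.34e-27), GREB1 by 3.11 ± 0.13 (adjusted p = 1.74e-15), PGR by 2.19 ± 0.14 (adjusted p = 1.83e-11) and ESR1 by 0.48 ± 0.07 on the log2 scale (adjusted p = 4.62e-06). NXPH3 (5.24 ± 0.24), SEMA3G (4.21 ± 0.22), FMN1 (4.21 ± 0.22) and the potassium channel gene KCNH1 (4.16 ± 0.18) were the other largest rises among genes with a mean of at least 5 CPM. TFF1 changed from 3.67 to 5.12 CPM (0.48 ± 0.17, adjusted p = 0.0341), a call lost in 6 alternative settings, including those without T47D vehicle replicate 2 (0.42) or 3 (0.42) or without any of the 3 E2 libraries (0.48 to 0.50). CCND1 (0.11 ± 0.04, adjusted p = 0.0839), PDZK1 (0.74 ± 0.52, adjusted p = 0.252) and MKI67 (0.40 ± 0.24, adjusted p = 0.271) were not called, although CCND1 passed without T47D vehicle replicate 2 (0.147) and with the 1 CPM filter (0.123), and MKI67 without a filter (0.421). The transcription factor gene SOX2 fell by 1.66 on the log2 scale (SE 0.12), EGLN3 by 1.60 (SE 0.08) and AMIGO2 by 1.51 (SE 0.05). In all, 1824 genes were higher and 1629 lower, of which 307 and 114 changed at least 2-fold, and a fit of these 6 libraries alone called 2064, 1262 higher and 802 lower. The balance turned to 1934 higher and 2467 lower with length and GC trends removed and to 1694 and 1762 without scaling.

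Among the gene groups at 4 hours in T47D, 33 of 37 estrogen-induced genes were higher and 0 lower (median 1.53, camera adjusted p = 2.21e-53). RET, a receptor tyrosine kinase gene, rose by 3.72 ± 0.19. Further, 11 of 14 estrogen-repressed genes were lower and 0 higher (median -0.52, camera adjusted p = 6.61e-13), including the antiproliferative gene BTG2 (-0.94 ± 0.05). MYC targets were higher in 35 of 53 cases and lower in 0 (median 0.34, camera adjusted p = 2.39e-18), for example NOP16 (0.89 ± 0.08). Aminoacyl-tRNA synthetase genes were higher in 11 of 18 and lower in 0 (median 0.18, camera adjusted p = 1.23e-05, and adjusted p = 0.139 with an estimated correlation). Cell cycle genes had barely moved. Of the 40 G1/S genes, 4 were lower and 0 higher (median -0.06, camera adjusted p = 0.0363, and adjusted p = 0.429 with an estimated correlation), and the adjusted p was 0.0783 and 0.176 without T47D vehicle replicate 2 or 3, 0.0778 and 0.142 without E2 replicate 1 or 2. Of the 53 G2/M genes, 8 were lower and 1 higher (median -0.08, camera adjusted p = 0.0131, and adjusted p = 0.212 with an estimated correlation), and the adjusted p was 0.0759 and 0.0893 without T47D vehicle replicate 2 or 3 and 0.0845 without E2 replicate 2. Interferon-stimulated genes were lower in 22 of 29 cases and higher in 0 (median -0.62, camera adjusted p = 8.45e-11, and adjusted p = 0.139 with an estimated correlation). OAS1 (-1.79 ± 0.32) and IFIT1 (-1.70 ± 0.30) fell most. The vehicle libraries spread widely for these genes, with IFIT1 at 36.6 ± 18.3 CPM, and without T47D vehicle replicate 2 the median was -0.43 with 15 members lower. Higher and lower counts adjusted over the list alone were 35 and 0 for estrogen-induced, 0 and 12 for estrogen-repressed, 37 and 0 for MYC target, 1 and 6 for G2/M and 0 and 23 for interferon-stimulated genes, with no difference in the other lists named here.

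After 24 hours of E2, T47D cells had raised cell cycle genes along with the estrogen-responsive ones. Vehicle was sampled at 4 hours, so this comparison changes hormone and time in culture together. MYC reached 19.99 ± 1.49 CPM (log2 change 3.52 ± 0.15, adjusted p = 1.09e-21), CXCL12 126.2 ± 5.59 CPM (6.51 ± 0.13, adjusted p = 3.26e-31) and PDZK1 3.95 ± 0.716 CPM (3.51 ± 0.44, adjusted p = 3.43e-11). GREB1 rose by 3.43 ± 0.13 (adjusted p = 6.82e-17), PGR by 2.22 ± 0.14 (adjusted p = 2.49e-12), TFF1 by 1.26 ± 0.16 (adjusted p = 3.05e-08), CCND1 by 0.93 ± 0.04 (adjusted p = 9.06e-17) and ESR1 by 0.74 ± 0.07 on the log2 scale (adjusted p = 3.58e-10). MKI67 rose by 0.66 ± 0.24 (adjusted p = 0.022), but not past the test in a fit of the 6 libraries alone (0.673), without T47D vehicle replicate 1 (0.42) or without E2 24 h replicate 1 (0.59) or 3 (0.37). NKAIN1 (5.64 ± 0.21), NXPH3 (5.53 ± 0.24), the transporter gene SLC47A1 (5.37 ± 0.23) and the transglutaminase gene TGM2 (5.31 ± 0.30) were the next largest rises after CXCL12 among genes with a mean of at least 5 CPM. SLC37A2 (-4.66 ± 0.20), STON1 (-3.87 ± 0.21) and the muscarinic receptor gene CHRM1 (-3.34 ± 0.17) were among the largest falls at that level. In all, 4974 genes were higher and 5213 lower, of which 1000 and 1347 changed at least 2-fold. The balance depended on the setting, with 5354 and 4887 without a filter and 4476 and 6396 with trends removed.

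All 40 G1/S genes were higher at 24 hours in T47D (median 1.04, camera adjusted p = 1.81e-25). DTL (1.90 ± 0.05) and the replication licensing gene CDC6 (1.82 ± 0.04) were among them. Of the G2/M genes, 40 of 53 were higher and 2 lower (median 0.34, camera adjusted p = 5e-08), including TACC3 (0.75 ± 0.05). Of 17 G1 regulators, 12 were higher and 4 lower (median 0.54, camera adjusted p = 0.00227). CDC25A, a phosphatase gene (1.91 ± 0.07), E2F2 (1.82 ± 0.09) and the cyclin gene CCNE1 (1.75 ± 0.08) rose most. MYC targets were higher in 51 of 53 cases and lower in 0 (median 0.82, camera adjusted p = 3.67e-21), for example NOP56 (1.31 ± 0.05). Estrogen-induced genes were higher in 36 of 37 and lower in 0 (median 2.20, camera adjusted p = 4.15e-26), and all 14 estrogen-repressed genes were lower (median -1.28, camera adjusted p = 1.63e-12). Of 20 genes of the ATF4 and amino acid response, 15 were higher and 1 lower (median 0.61, camera adjusted p = 2.28e-05). The hormone gene STC2 of this list rose by 4.54 ± 0.06 and the mTORC1 inhibitor gene DDIT4 fell by 2.58 on the log2 scale (SE 0.09). Interferon-stimulated genes were lower in 25 of 29 and higher in 1 (median -0.88, camera adjusted p = 9.72e-06, and adjusted p = 0.261 with an estimated correlation), beside the vehicle spread given above. When adjusted over the list alone, 52 MYC targets were higher and 41 G2/M genes were higher and 4 lower, and the counts of the other lists named here did not differ.

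In TYS, 4 hours of E2 changed few genes. Only 6 of 16512 genes were called by edgeR, with 852 at an unadjusted p under 0.05, and DESeq2 called 30 and limma-voom 10. KDM4B, the gene of a histone demethylase, rose from 105.2 ± 3.18 to 153.6 ± 3.95 CPM (log2 change 0.55 ± 0.05, adjusted p = 1.42e-07) and was called in every alternative run. The kinase gene SGK3 (0.52 ± 0.09, adjusted p = 0.00575) and SEC14L2 (0.46 ± 0.09, adjusted p = 0.0376) were the others called higher. MYC was lower, at 23.7 ± 2.08 against 31.8 ± 2.22 CPM (-0.42 ± 0.07, adjusted p = 0.00575), with ENC1 (-0.44 ± 0.07, adjusted p = 0.00575) and the kinase gene PLK2 (-0.26 ± 0.04, adjusted p = 0.00575). These calls, other than KDM4B, were lost in a fit of the 6 libraries alone and when single libraries were left out, MYC without TYS vehicle replicate 1 (-0.40) or E2 replicate 2 (-0.37) or 3 (-0.42). The count was 1 without TYS vehicle replicate 1 or E2 replicate 2, 3 without vehicle replicate 2 or E2 replicate 3, and 25 without vehicle replicate 3. CXCL12 (0.00 ± 0.04), GREB1 (0.13 ± 0.11), PGR (0.11 ± 0.13), TFF1 (-0.19 ± 0.12), ESR1 (0.06 ± 0.07), CCND1 (-0.08 ± 0.04), PDZK1 (0.32 ± 0.31) and MKI67 (-0.01 ± 0.24) had an adjusted p = 1. The estrogen-induced list had 1 member higher and 0 lower (2 and 0 adjusted over the list alone, median 0.05, camera adjusted p = 0.00966, and adjusted p = 0.131 with an estimated correlation), with an adjusted p = 0.156 without E2 replicate 1. No member of the MYC target list (median -0.06, camera adjusted p = 3.16e-07, and adjusted p = 0.376 with an estimated correlation) or of the 9 heat shock genes (median 0.09, camera adjusted p = 0.00019, and adjusted p = 0.131 with an estimated correlation) was called over all genes, against 0 and 1 adjusted over the list alone.

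After 24 hours of E2 in TYS, again set against the 4 hour vehicle, cell cycle genes were lower rather than higher. Of the 40 G1/S genes, 31 were lower and 0 higher (median -0.25, camera adjusted p = 3.79e-23). CDC45 (-0.42 ± 0.05) and MCM5 (-0.36 ± 0.04) were examples. Of the 53 G2/M genes, 32 were lower and 0 higher (median -0.21, camera adjusted p = 2.78e-19), for example PLK1 (-0.39 ± 0.06). Of 17 G1 regulators, 8 were lower and 1 higher (median -0.19, camera adjusted p = 0.000256), including CCNE1 (-0.38 ± 0.07) and the cyclin gene CCND3 (-0.38 ± 0.06). MYC (0.02 ± 0.06, adjusted p = 0.904), CCND1 (-0.01 ± 0.04, adjusted p = 0.955), CXCL12 (-0.07 ± 0.04, adjusted p = 0.33), GREB1 (0.22 ± 0.11, adjusted p = 0.185), PGR (0.15 ± 0.13, adjusted p = 0.474), ESR1 (-0.01 ± 0.07, adjusted p = 0.921) and MKI67 (-0.64 ± 0.24, adjusted p = 0.0736) were not called. MKI67 passed by DESeq2 (-0.652), without a filter (-0.67), in a fit of the 6 libraries alone (-0.635) and with length and GC trends removed (-0.502). GREB1 passed in the last 3 of these (0.188, 0.222 and 0.265) and PGR in the last 2 (0.154 and 0.317). TFF1 fell from 10.2 ± 1.53 to 3.15 ± 0.548 CPM (-1.69 ± 0.17, adjusted p = 1.12e-08) and PDZK1 rose from 1.07 to 2.82 CPM (1.41 ± 0.28, adjusted p = 0.000199). The light-sensitive receptor gene OPN3 (1.15 ± 0.08), NKAIN1 (1.12 ± 0.09) and the mTOR inhibitor gene DEPTOR (1.04 ± 0.10) were among the largest rises of genes with a mean of at least 5 CPM, and GPNMB (-1.26 ± 0.15) and DOCK10 (-1.03 ± 0.08) among the largest falls. In all, 1503 genes were higher and 1342 lower, of which 101 and 33 changed at least 2-fold. The balance depended on the setting, with 2087 higher and 845 lower without scaling, 1052 and 1895 without a filter and 1331 and 1763 by DESeq2. The total was 1835 without E2 24 h replicate 2 and 4749 in a fit of the 6 libraries alone.

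Other groups also moved in TYS at 24 hours. Estrogen-induced genes were higher in 14 of 37 cases and lower in 4 (median 0.11, camera adjusted p = 0.00385). Estrogen-repressed genes were higher in 7 of 14 cases and lower in 3 (median 0.13, camera adjusted p = 0.0379, and adjusted p = 0.26 with an estimated correlation), with an adjusted p = 0.0873 without TYS vehicle replicate 1 and 0.0599 without E2 24 h replicate 1. TP53INP1, known as a stress gene (0.68 ± 0.11), and MXD4, a gene of the MAX network (0.59 ± 0.06), were higher, and IL1R1 was lower (-0.75 ± 0.16). Of 20 ATF4 and amino acid response genes, 8 were higher and 1 lower (median 0.12, camera adjusted p = 6.14e-05), including the asparagine synthetase gene ASNS (1.02 ± 0.06) and the cystine transporter gene SLC7A11 (0.86 ± 0.15). Of 9 heat shock genes, 5 were lower and 0 higher (median -0.22, camera adjusted p = 6.14e-05), including HSPH1 (-0.37 ± 0.04). MYC targets were lower in 18 of 53 cases and higher in 0 (median -0.15, camera adjusted p = 9.59e-10, and adjusted p = 0.103 with an estimated correlation), for example TCOF1 (-0.37 ± 0.04) and the nucleolin gene NCL (-0.33 ± 0.05). Adjusted over the list alone, the counts higher and lower were 0 and 35 for G1/S, 0 and 43 for G2/M, 0 and 23 for MYC target, 10 and 1 for ATF4 and 0 and 6 for heat shock genes, with no difference in the other lists named for TYS at 24 hours.

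TDG kept a response to E2 that was seen at 4 hours. CXCL12 rose from 101.9 ± 5.08 to 203.1 ± 7.53 CPM (log2 change 0.99 ± 0.04, adjusted p = 4.87e-15), PGR by 0.93 ± 0.13 (adjusted p = 4.62e-05), GREB1 by 0.78 ± 0.11 (adjusted p = 4.53e-05) and CCND1 by 0.30 ± 0.04 (adjusted p = 2.05e-05). MYC was level, at 22.1 CPM in vehicle and 22.0 CPM in E2 libraries (0.00 ± 0.07, adjusted p = 0.992). TFF1 (-0.10 ± 0.21, adjusted p = 0.858), PDZK1 (0.84 ± 0.33, adjusted p = 0.107), ESR1 (0.07 ± 0.07, adjusted p = 0.693) and MKI67 (0.27 ± 0.24, adjusted p = 0.65) were not called. PDZK1 passed by DESeq2 (0.842), in a fit of the 6 libraries alone (0.842) and without a filter (0.848), as did MKI67 without a filter (0.279). Among genes with a mean of at least 5 CPM, KCNH1 (1.37 ± 0.10), NXPH3 (1.34 ± 0.07), RAPGEFL1 (1.31 ± 0.05) and the neuropeptide receptor gene NPY1R (1.31 ± 0.09) rose most, and GRHL3 (-1.06 ± 0.10) and SHISA2 (-0.96 ± 0.06) fell most. Of the estrogen-induced genes, 28 of 37 were higher and 0 lower (median 0.63, camera adjusted p = 8.37e-57), and of the estrogen-repressed genes, 8 of 14 were lower and 0 higher (median -0.32, camera adjusted p = 1.05e-16). Of the ATF4 and amino acid response genes, 6 of 20 were higher and 2 lower (median 0.13, camera adjusted p = 0.00344, and adjusted p = 0.228 with an estimated correlation), with STC2 1.97-fold higher. MYC targets had 1 of 53 higher and 0 lower (median 0.06, camera adjusted p = 0.00145, and adjusted p = 0.491 with an estimated correlation), with an adjusted p = 0.159 without E2 replicate 1. Mitochondrially encoded genes were lower in 8 of 13 cases and higher in 0 (median -0.47, camera adjusted p = 8.15e-12, and adjusted p = 0.144 with an estimated correlation), set against TDG vehicle libraries that differed for this list as given above. The counts adjusted over the list alone, higher and lower, were 31 and 0 for estrogen-induced, 0 and 11 for estrogen-repressed, 7 and 3 for ATF4 and 0 and 13 for mitochondrial genes. In all, 426 genes were higher and 310 lower, and the total was 485 without TDG vehicle replicate 2 and 1137 in a fit of the 6 libraries alone.

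At 24 hours, again set against the 4 hour vehicle, TDG showed higher estrogen-induced genes and slightly lower mitotic genes. PDZK1 rose from 0.86 ± 0.0968 to 9.97 ± 0.453 CPM (log2 change 3.53 ± 0.28, adjusted p = 8.9e-13), the tau gene MAPT by 2.68 ± 0.15, NKAIN1 by 2.64 ± 0.10 and the kinase gene SGK1 by 2.39 ± 0.15. CXCL12 rose by 0.89 ± 0.04 (adjusted p = 1.35e-14), GREB1 by 0.88 ± 0.11 (adjusted p = 2.73e-06), PGR by 0.85 ± 0.13 (adjusted p = 4.97e-05), CCND1 by 0.46 ± 0.04 (adjusted p = 3.93e-09) and MYC by 0.28 ± 0.07 (adjusted p = 0.00523). TFF1 was lower, at 1.23 against 2.72 CPM (-1.15 ± 0.26, adjusted p = 0.000306). ESR1 (0.08 ± 0.07, adjusted p = 0.452) and MKI67 (-0.18 ± 0.24, adjusted p = 0.654) were not called, although MKI67 passed without a filter (-0.18). Estrogen-induced genes were higher in 33 of 37 cases and lower in 2 (median 0.78, camera adjusted p = 3.17e-39), and estrogen-repressed genes lower in 9 of 14 and higher in 0 (median -0.40, camera adjusted p = 2.56e-12). Of the 53 G2/M genes, 23 were lower and 0 higher (median -0.14, camera adjusted p = 1.32e-10), for example the cyclin gene CCNB2 (-0.48 ± 0.05). Hypoxia and glycolysis genes were higher in 13 of 24 and lower in 0 (median 0.23, camera adjusted p = 1.26e-06), with PFKFB3 1.99-fold higher, and ATF4 and amino acid response genes in 8 of 20 with 2 lower (median 0.18, camera adjusted p = 3.09e-05). MYC targets were higher in 10 of 53 and lower in 0 (median 0.09, camera adjusted p = 0.00263, and adjusted p = 0.474 with an estimated correlation). Mitochondrially encoded genes were lower in 11 of 13 and higher in 0 (median -0.54, camera adjusted p = 7.85e-10, and adjusted p = 0.0896 with an estimated correlation), against the same vehicle libraries as at 4 hours. Adjusted over the list alone, the counts higher and lower were 35 and 2 for estrogen-induced, 0 and 11 for estrogen-repressed, 0 and 28 for G2/M, 14 and 0 for hypoxia, 11 and 2 for ATF4 and 0 and 13 for mitochondrial genes, with no difference in the MYC targets. In all, 1779 genes were higher and 1514 lower, against 2130 and 2337 with trends removed.

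**Figure D4:**
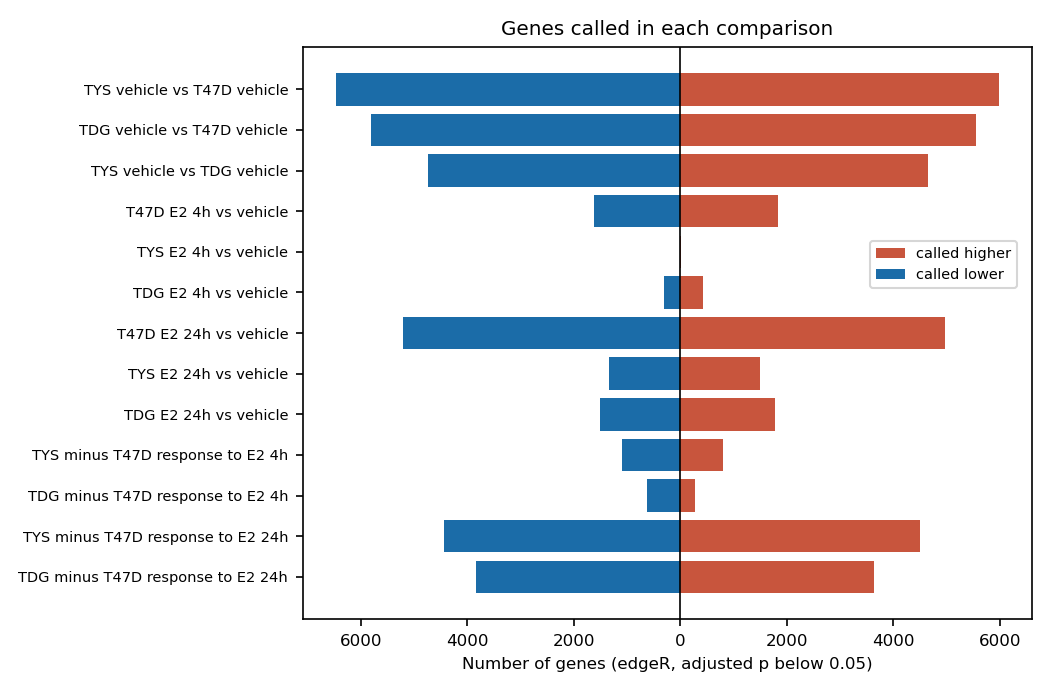
Number of genes called higher (right) and lower (left) by edgeR at an adjusted p below 0.05 in each of the 13 comparisons. TYS after 4 hours of E2 has 6 genes in all, against 3453 in T47D and 736 in TDG.

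The difference between lines in the response to E2 was tested directly with interaction terms. TYS and TDG differed from T47D in routine serum as well as in ESR1, and these cannot be separated here. The mutant lines also started from other vehicle levels. MYC lay at 31.8 CPM in TYS vehicle and 22.1 CPM in TDG vehicle against 1.74 CPM in T47D vehicle. CXCL12 lay at 540.5 CPM in TYS vehicle and 101.9 CPM in TDG vehicle, against 43.4 CPM in T47D after 4 hours of E2. A smaller response therefore does not mean a lower level after E2. At 4 hours the response of MYC was smaller in TYS than in T47D by a log2 difference of -3.49 ± 0.16 (adjusted p = 2.24e-18) and in TDG by -3.07 ± 0.16 (adjusted p = 1.78e-16). The differences for CXCL12 were -4.97 ± 0.14 (adjusted p = 2.01e-25) and -3.97 ± 0.14 (adjusted p = 1.81e-22), for GREB1 -2.98 ± 0.17 (adjusted p = 2.32e-12) and -2.33 ± 0.17 (adjusted p = 3.51e-10), and for PGR -2.08 ± 0.19 (adjusted p = 2.2e-08) and -1.26 ± 0.19 (adjusted p = 7.43e-05). For ESR1 they were -0.43 ± 0.10 (adjusted p = 0.00372) and -0.41 ± 0.10 (adjusted p = 0.00932), and for CCND1 -0.19 ± 0.06 (adjusted p = 0.0477) and 0.19 ± 0.06 (adjusted p = 0.0726). The CCND1 call in TYS was lost in 12 of 22 settings, among them the fit of only the compared libraries (-0.18), that without a filter (-0.216) and those without any of the 3 T47D E2 libraries (-0.21 to -0.194). In TDG it was gained in 4, among them DESeq2 (0.187). Of the estrogen-induced genes, 32 of 37 responded less in TYS and 0 more (median -1.15, camera adjusted p = 5.88e-62), and 27 less in TDG and 0 more (median -0.90, camera adjusted p = 5.64e-51). Of the 53 MYC targets, 34 responded less in TYS (median -0.41, camera adjusted p = 2.04e-23) and 21 less in TDG (median -0.27, camera adjusted p = 1.06e-18), and 0 more in either. Interferon-stimulated genes had a higher response in 7 of 29 cases in TYS (median 0.62, camera adjusted p = 2.51e-06, and adjusted p = 0.248 with an estimated correlation). In TDG 16 of 29 did (median 1, camera adjusted p = 4.35e-22, and adjusted p = 0.0345 with an estimated correlation), with 0 lower in both lines. The list's own median at 4 hours was -0.62 in T47D, 0.01 in TYS and 0.19 in TDG. In TYS 0 members were called and in TDG 2 were called higher. The TYS difference thus mirrors the fall in T47D rather than a rise in TYS. These values stand beside the spread of the T47D vehicle libraries for these genes. List means were 2.46, 2.56 and 3.06 log2 CPM in TDG vehicle against 2.96 to 3.04 in TDG after E2. For TYS and TDG, the counts adjusted over the list alone were 34 and 30 estrogen-induced genes and 35 and 29 MYC targets with a smaller response. They were 0 and 2 estrogen-induced genes with a larger response and 12 and 21 interferon-stimulated genes with a higher one. In all, 804 genes had a higher and 1103 a lower response in TYS than in T47D, and 276 and 631 in TDG. With trends removed TYS had 1382 higher and 1338 lower. Without both T47D libraries that stood apart, the total for TDG was 1521 in place of 907.

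Vehicle was sampled at 4 hours, so the interactions at 24 hours compare the lines for hormone and time in culture together. They covered more genes, 4508 with a higher and 4446 with a lower response in TYS and 3637 and 3843 in TDG. These balances depended on the setting, with 5306 and 3720 in TYS and 4204 and 3292 in TDG without scaling, 5547 and 4135 and 4716 and 3710 with length and GC trends removed, and 4306 and 5015 and 3603 and 4275 without both T47D libraries that stood apart. Vehicle levels matter here too. Of 1000 genes at least 2-fold higher in T47D at 24 hours, 46.9% in TYS vehicle and 29.6% in TDG vehicle already lay past that level. For the 1347 genes at least 2-fold lower these were 65.3% and 50.8%. The response of MYC was smaller than in T47D by -3.50 ± 0.16 in TYS (adjusted p = 5.74e-19) and -3.24 ± 0.16 in TDG (adjusted p = 1.23e-17). For TFF1 the differences were -2.96 ± 0.23 (adjusted p = 2.98e-12) and -2.41 ± 0.31 (adjusted p = 1.93e-08), and for CCND1 -0.94 ± 0.06 (adjusted p = 3.31e-13) and -0.47 ± 0.06 (adjusted p = 3.93e-07). For ESR1 they were -0.76 ± 0.10 (adjusted p = 2.57e-07) and -0.66 ± 0.10 (adjusted p = 3.64e-06). PDZK1 responded less in TYS (-2.09 ± 0.52, adjusted p = 0.000143, and -2.698 without T47D vehicle replicate 3), and its difference in TDG was 0.03 ± 0.52 (adjusted p = 0.983). All 40 G1/S genes responded less in TYS (median -1.25, camera adjusted p = 1.08e-29) and in TDG (median -0.99, camera adjusted p = 1.88e-31), for example CDC6 (-2.14 ± 0.06 and -1.65 ± 0.06) and DTL (-2.13 ± 0.07 and -1.76 ± 0.07). G2/M genes responded less in 45 of 53 cases in TYS and more in 1 (median -0.53, camera adjusted p = 8.9e-13), and less in 47 and more in 0 in TDG (median -0.47, camera adjusted p = 7.54e-16). MYC targets responded less in 51 of 53 cases in TYS (median -0.97, camera adjusted p = 5.78e-23) and 47 in TDG (median -0.68, camera adjusted p = 5.46e-22), and estrogen-induced genes in 36 of 37 (median -2.02, camera adjusted p = 2.89e-26) and 32 with 1 more (median -1.37, camera adjusted p = 5.46e-22). When adjusted over the list alone, 46 G2/M genes in TYS and 49 MYC targets and 33 estrogen-induced genes in TDG responded less, with no difference in the other counts given here.

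The genes that differed in T47D between 24 hours of E2 and the 4 hour vehicle, a comparison of hormone and time in culture together, were set against the state of the mutant lines without hormone. Of the 1000 genes at least 2-fold higher after 24 hours, 80.1% were called higher in TYS vehicle and 77.4% in TDG vehicle than in T47D vehicle, while 7.8% and 5.3% were called lower. Of all 16512 genes, 5979 and 5552 were called higher. Of the 1347 genes at least 2-fold lower, 85.3% were called lower in TYS and 81.8% in TDG, and of all genes 6466 and 5799. At 4 hours, with a vehicle of the same time, the 307 genes raised at least 2-fold by E2 were called higher in 70.7% of cases in TYS vehicle and 63.8% in TDG vehicle, and the 114 lowered ones called lower in 75.4% and 67.5%. Without the 2-fold limit, TYS vehicle shared 1266 higher and 1107 lower genes with the 4 hour response and TDG vehicle 1164 and 1068, where lists drawn independently would share 660.5, 637.9, 613.3 and 572.1. The T47D vehicle libraries enter both sides of this comparison too, and 20 simulations without any change gave means of 0.45, 0.1, 0.25 and 0.1 shared calls. For the 24 hour genes without the 2-fold limit, 3778 genes were higher both after 24 hours and in TYS vehicle and 3670 both after 24 hours and in TDG vehicle, where lists drawn independently would share 1801.1 and 1672.5. For lower genes these were 4077 and 3947 against 2041.4 and 1830.8. TYS and TDG shared 4274 genes called higher and 4694 called lower against T47D vehicle, where lists drawn independently would share 2010 and 2271. These comparisons use the same T47D vehicle libraries, which alone gave means of 2.2 and 1.25 calls shared by TYS and TDG in 20 simulations without any change, and of 2.85 and 1.65 shared by TYS and T47D E2 24 h and 1.75 and 1.45 shared by TDG and T47D E2 24 h. The 3 vehicle libraries are too few to give 2 sets of 2, so part of the excess may come from sharing them. TYS and TDG also had in common a routine charcoal-dextran treated serum that T47D did not have. With 1 line per genotype, its part in the shared calls cannot be told apart from that of ESR1. The log2 changes of T47D E2 24 h correlated across genes at r = 0.629 with those of TYS vehicle and 0.676 with those of TDG vehicle. Between TYS and TDG vehicle r was 0.745. In the same order, the simulations without any change gave r = 0.524, 0.518 and 0.509. Covariances were 0.746, 0.594 and 1.12 against 0.0357, 0.0358 and 0.0358 in the simulations.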

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

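The tests in this part were chosen after the results were seen, except the thinning of libraries to one total, the interaction terms, limma-voom and the fits of only the compared libraries or without single libraries. By an interaction term, the response to E2 differed from that of T47D for 1907 genes in TYS and 907 in TDG at 4 hours. At 24 hours the terms covered 8954 and 7480 genes, where hormone and time in culture change together.

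The log2 differences of MYC were -3.49 (TYS) and -3.07 (TDG) at 4 hours and -3.50 and -3.24 at 24 hours. At 4 hours in TYS the differences were 1.83 for SOX2, 1.62 for EGLN3, 1.32 for DBP, 1.30 for MX1, -5.15 for NXPH3, -4.97 for CXCL12, -4.17 for FMN1 and -4.07 for SEMA3G. None of these genes was called in TYS itself at 4 hours, and SOX2 and EGLN3 fell in T47D, as given above. At 4 hours in TDG the differences were 2.69 for OAS1, 2.47 for IFIT1, 1.79 for MX1, 1.66 for ISG15, -3.97 for CXCL12, -3.90 for NXPH3, -3.25 for FMN1 and -3.18 for SEMA3G. The interferon-stimulated genes among these depended on the setting. MX1 in TYS was no longer called in 9 settings, among them only the compared libraries (1.313), limma-voom (1.147) and the fits without any of the 3 TYS vehicle libraries (1.321, 1.319 and 1.219), and it was 0.658 without T47D vehicle replicate 2. ISG15 in TDG was not called without T47D vehicle replicate 2 (1.297, adjusted p = 0.0652), T47D E2 4 h replicate 1 (1.579), TDG vehicle replicate 1 (1.56) or 2 (1.555) or TDG E2 4 h replicate 1 (1.567). MX1 in TDG was 1.144 without T47D vehicle replicate 2 and IFIT1 was 3.16 without TDG vehicle replicate 3, both still called. At 24 hours in TYS they were 3.36 for PIK3IP1, 3.08 for SERHL2, 2.92 for DDIT4, 2.77 for ATP13A4, -6.58 for CXCL12, -5.19 for SLC47A1, -5.18 for ACOX2 and -4.93 for SEMA3G. Without TYS E2 24 h replicate 1, ATP13A4 was 2.006 and not called (adjusted p = 0.0548). At 24 hours in TDG they were 3.40 for NDRG1, 2.80 for SERHL2, 2.5 for AQP3, 2.42 for ADGRF1, -5.62 for CXCL12, -4.27 for ACOX2, -3.94 for OLFM1 and -3.88 for SEMA3G.

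T47D vehicle replicate 1 and T47D E2 24 h replicate 2 stood apart from their replicates. The weaker of their correlations with transcript length was -0.702, a trend that may account for their position. Correlations with GC content were 0.459 for T47D vehicle replicate 1 and 0.094 for T47D E2 24 h replicate 2. Libraries of the other 7 groups reached 0.575 in size. The value of 0.094 argues against a GC trend for T47D E2 24 h replicate 2. For T47D vehicle replicate 1 a part of GC content stays open. A wrong label was argued against because each of the 2 libraries correlated best with a library of its own group. No biological explanation was tested.

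Interferon-stimulated genes were lower in T47D after 4 hours of E2. With the length and GC trends removed the median log2 change was -0.69, which argues against a length trend as the whole cause. A single vehicle library may contribute, since the median was -0.43 with 15 members lower without T47D vehicle replicate 2. A fluctuation between cultures shared by these genes stays open, with a gap of 0.41 log2 CPM between the lowest vehicle and the highest E2 list mean and 3 cultures per group. An effect of E2 cannot be told apart from it.

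G1/S genes were lower in TYS after 24 hours of E2 than in the 4 hour vehicle. With the 6 libraries thinned to one total the median stayed at -0.25. Counts are scaled to the library total in either case, so thinning was not expected to move the median and cannot decide on library size. With the length and GC trends removed the median was again -0.25, so that transcript length does not account for it. Time in culture changes together with hormone in each line and cannot be told apart from E2, and the median of the same list in TDG was 0.05. An effect of E2 in TYS stays open.

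The 6 libraries of each comparison between groups make 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 12445 and 276 for TYS against T47D vehicle, 11351 and 0 for TDG against T47D vehicle, 9389 and 0 for TYS against TDG vehicle, 3453 and 0 for T47D at 4 hours, 736 and 0 for TDG at 4 hours, 10187 and 1776 for T47D at 24 hours, 2845 and 0 for TYS at 24 hours and 3293 and 0 for TDG at 24 hours. In each of these, 1 split, the real one, gave as many genes. For TYS at 4 hours 2 of the 10 splits did, with 6 genes in the real one and 7 in the highest other. The other splits mix libraries of both groups, which puts the difference between the groups into the spread. That mixing lowers their counts, so these splits do not measure chance.

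For the interactions, 20 draws that regrouped the 12 libraries across lines were set beside the real split. At 4 hours, 2 of 21 splits gave as many genes for TYS, with 1907 in the real split and 10617 in the highest other, and 2 of 21 for TDG, with 907 and 12318. In both, a draw calling several times the real count points to a structure of the samples, the difference between the lines, and the next highest draws gave 0 and 80. At 24 hours, 1 of 21 did for each line, the real one, with 8954 against 6693 for TYS and 7480 against 6797 for TDG. Since these draws mix lines, they do not measure chance. In a limma fit that kept the effects of line and E2 and exchanged only the residuals of the 12 libraries, the real split and 100 draws were counted. The real split alone, 1 of 101, gave as many genes for TYS at 4 hours (1926 against 621 in the highest other), TDG at 4 hours (936 against 397) and TYS at 24 hours (9143 against 6404), and 2 of 101 did for TDG at 24 hours (7564 against 7983). For the 4 counts the share of draws was thus under 0.05. Exchanging the residuals of single libraries cannot exclude a fluctuation shared by the cultures of a group.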

How the results depend on the processing

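The fits without both T47D libraries with a length trend and with length and GC trends removed were chosen after the data were seen. Outside the omission of single libraries, 114 of 125 counts of genes, 3902 of 3967 values of named genes, 696 of 740 values of lists and 14 of 14 values of overlaps kept their direction and side of the threshold, or for counts stayed within 1.5 times. With single libraries left out, these were 95 of 102 counts, 2754 of 2880 gene values and 580 of 600 list values. A fit of only the compared libraries called 2064 genes in T47D, 2 in TYS and 1137 in TDG at 4 hours and 4749 in TYS at 24 hours. In the main fit these counts were 3453, 6, 736 and 2845. The smaller fit estimates dispersion from fewer libraries. The count fell in T47D and TYS at 4 hours and rose in the other comparisons given. The size of the contrast in counts between lines thus depends on the libraries fitted. Its order at 4 hours, T47D above TDG above TYS, was the same in both fits. The count in TYS at 4 hours was 31 without a filter, 10 by limma-voom, 30 by DESeq2 and 29 with trends removed. With trends removed TDG at 4 hours gave 1180, and the TDG interaction at 4 hours gave 1439, against 1521 without both T47D libraries. Leaving out single libraries gave 1 to 25 genes in TYS at 4 hours (1 without vehicle replicate 1, 25 without vehicle replicate 3), 485 to 742 in TDG at 4 hours and 1835 to 2258 in TYS at 24 hours. The replicate block called 12430 genes in TYS vehicle. Libraries of the same replicate number correlated at -0.269 to 0.167, which does not settle whether the numbers pair libraries. In TDG against T47D vehicle these correlations were 0.117, 0.044 and 0.035, against at most 0.04 for other numbers. In T47D at 24 hours other numbers reached 0.414. Without scaling, the median of all genes moved to -0.105 in TYS against T47D vehicle and 0.138 in the TYS interaction at 24 hours, and TYS at 24 hours had 2087 higher and 845 lower. The larger side turned between higher and lower in at least 1 setting in 10 of 13 comparisons, for example in T47D at 4 hours with trends removed (1934 higher and 2467 lower) and in the TDG interaction at 24 hours without scaling (4204 and 3292). In TYS at 24 hours the balance turned to 1360 and 1583 with DESeq2 size factors, 1331 and 1763 by DESeq2, 1052 and 1895 without a filter, 1424 and 1589 with the 1 CPM filter and 2248 and 2501 with only the compared libraries. Reversed values lay near 0. They were -0.003 for ESR1 in TDG vehicle without both T47D libraries, and, without scaling, 0.006 for CXCL12 and 0.005 for MKI67 in TYS at 4 hours and 0.028 for ESR1 and 0.038 for CCND1 in TYS at 24 hours. For MYC they were 0.003 (no filter) and 0.017 (trends removed) in TDG at 4 hours and -0.018 (no filter) and -0.009 (trends removed) in TYS at 24 hours, where ESR1 was 0.011 with trends removed. Over single libraries left out, ranges that crossed 0 were -0.008 to 0.18 for ESR1 in TDG vehicle, -0.023 to 0.007 for CXCL12, -0.147 to 0.107 for MKI67 and -0.009 to 0.172 for PGR in TYS at 4 hours, -0.032 to 0.029 for MYC and -0.289 to 0.03 for TFF1 in TDG at 4 hours, and -0.049 to 0.014 for CCND1 and -0.052 to 0.026 for MYC in TYS at 24 hours. The cause was not tested. Among lists, adjusted p-values over single libraries left out were 0.0124 to 0.176 for G1/S and 0.000736 to 0.0893 for G2/M genes in T47D at 4 hours, 0.0231 to 0.094 for G2/M genes between TYS and TDG vehicle, 0.852 to 0.992 for cholesterol genes in TYS vehicle, 1.38e-05 to 0.239 for ribosomal genes in TDG vehicle, 0.00301 to 0.156 for estrogen-induced genes in TYS at 4 hours, 0.0195 to 0.0873 for estrogen-repressed genes in TYS at 24 hours and 3.11e-05 to 0.159 for MYC targets in TDG at 4 hours. The cholesterol list in TYS vehicle turned direction at 0.743 without a filter and 0.979 with only the compared libraries. Ribosomal genes in TDG vehicle had 0.00744 without a filter, 1.13e-06 without both T47D libraries and 0.0324 with trends removed, luminal markers there 0.0559 with only the compared libraries, estrogen-repressed genes in TYS at 24 hours 0.0621 with only the compared libraries and 0.0506 with trends removed, G2/M genes between TYS and TDG vehicle 0.0717 with trends removed, and G1/S genes in T47D at 4 hours 0.133 without a filter, 0.0615 with the 1 CPM filter and 0.0609 with only the compared libraries. With an estimated correlation the adjusted p was 0.195 for synthetases, 0.402 for ribosomal, 0.29 for interferon-stimulated and 0.0518 for luminal genes in TYS vehicle, and 0.0986 for synthetases, 0.316 for interferon-stimulated, 0.211 for luminal and 0.242 for hypoxia genes in TDG vehicle. Between TYS and TDG vehicle it was 0.339 for MYC targets, 0.113 for G1/S, 0.362 for G2/M, 0.171 for luminal, 0.426 for ribosomal, 0.516 for interferon-stimulated, 0.113 for hypoxia and 0.484 for mitochondrial genes. At 4 hours it was 0.429 for G1/S, 0.212 for G2/M, 0.139 for synthetases and 0.139 for interferon-stimulated genes in T47D, 0.131 for estrogen-induced genes, 0.376 for MYC targets and 0.131 for heat shock genes in TYS, and 0.491 for MYC targets, 0.228 for ATF4 and 0.144 for mitochondrial genes in TDG. At 24 hours it was 0.261 for interferon-stimulated genes in T47D, 0.103 for MYC targets and 0.26 for estrogen-repressed genes in TYS, and 0.474 for MYC targets and 0.0896 for mitochondrial genes in TDG, and for interferon-stimulated genes in the TYS interaction at 4 hours it was 0.248. The estimate allows for genes of a list that move together. Lists described as passing and not named here kept their call with it, some near the threshold. For MYC targets its adjusted p was 0.0358 in T47D at 4 hours and 0.0207 in TYS vehicle. In TYS at 24 hours it was 0.0352 for estrogen-induced, 0.039 for ATF4 and 0.039 for heat shock genes. In TDG at 24 hours it was 0.0344 for hypoxia and 0.0413 for ATF4 genes.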

Other observations

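The tests of this part were chosen after the results were seen, except those of the gene lists. Further gene groups in TYS against T47D vehicle went both ways. Cholesterol synthesis genes were higher in 9 of 24 cases and lower in 8 (median log2 change 0.02, mean -0.08, camera adjusted p = 0.961), where the median was -0.05 without scaling and -0.03 with length and GC trends removed. Basal and mesenchymal markers were higher in 5 of 14 and lower in 6 (median -0.27, camera adjusted p = 0.806). VIM was lower, at 0.181 ± 0.0262 CPM in TYS and 13.1 ± 1.95 CPM in T47D (n = 3). SNAI1 was higher, at 3.06 ± 0.394 CPM in TYS and 0.39 ± 0.0669 CPM in T47D. BCL2 family genes were higher in 6 of 12 and lower in 5 (median 0.22, mean -0.16, test direction down, camera adjusted p = 0.934). BCL2L1 had a log2 change of -1.21 and PMAIP1 of 1.13. Immediate early genes were higher in 3 of 11 and lower in 8 (median -0.36, mean 0.19, test direction down, camera adjusted p = 0.19). JUN had a log2 change of -1.99 and EGR3, with 2 counts in T47D vehicle, of 6.82. Adjusted over the list alone these counts were the same. Of markers of other cell types, 3 of 11 for fibroblasts, 2 of 11 for immune cells and 2 of 8 for endothelium were tested, with 1, 0 and 1 higher and 2, 2 and 0 lower in TYS than in T47D vehicle.

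A hypothesis was that the D538G line keeps part of the 4 hour response of T47D and the Y537S line less. Of the 307 genes raised at least 2-fold by E2 in T47D at 4 hours (median log2 change 1.83), 163 were called higher and 0 lower in TDG at 4 hours, with a median of 0.60. In TYS, 3 were called higher and 1 lower, with a median of 0.06. At 24 hours, against the 4 hour vehicle, the medians were 0.76 in TDG and 0.19 in TYS. These values are consistent with the hypothesis, which was formed and tested on the same libraries.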
